A study of Homo sapiens with 7 samples.

How the data were processed

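The series held 7 human cell line samples. The labels describe 2 replicates of eIF3a PAR-iCLIP in HEK293T and 5 m6A libraries made by miCLIP, from HEK293T after heat shock (1), HepG2 after heat shock (2) and HepG2 controls (2). Groups and replicate numbers came from the sample titles. The m6A libraries were not analysed here. Reads of the eIF3a samples were aligned to hg19 with Bowtie, and those of the m6A samples to hg19 with Novoalign, per the submitters' processing notes, which give no versions. The software that called the clusters, its filters, the treatment of duplicate reads and the way the replicates entered the list are not given in the sources used here.

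The authors deposited the eIF3a data as a list of intervals with a strand, a signal and a coverage profile. The signal in the deposited list was the highest read coverage of the cluster, in whole reads and without normalization, and equalled the maximum of the profile in every entry. The profile gave the coverage along the whole cluster as steps of length and height. The units were read from the values, since the list had no header. Column and strand were taken as deposited, and coordinates are printed counting from 1 with the file read as a 0-based list. The list does not say which replicate a read came from, or whether it holds reads of both, so no replicate could be left out, no replicate error could be given, and no comparison of groups was made. The depth of the libraries is unknown: the reads counted here are those in listed clusters, 39197 over all clusters and 36902 counting each distinct profile once, and they are not library totals. On the primary chromosomes, 22 clusters were merged into another that they overlapped on a strand. Reads common to such clusters are counted in each and added on merging.

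The number of reads and their start positions were recovered from each profile by splitting it into reads of 25 nt. All 3113 distinct profiles split exactly, with no position given a negative number of starts and no remainder. The splitting was tested on simulated data, 3113 profiles with known starts, of which 3113 (100%) were recovered exactly. The simulated reads were also 25 nt long, so this checks the arithmetic and not the read length. Entries of the same chromosome, strand and profile that fitted within the length of the profile were counted as 1 cluster, which turned 4013 entries into 3604 clusters. Unless stated otherwise, values refer to the 3566 clusters on the primary chromosomes. Their score and reads describe the whole cluster even where the listed interval is shorter, so the listed interval need not hold the summit. For neighbour analyses, clusters overlapping on a strand were first merged (3544 sites), and adjacent sites on opposite strands at most 1000 nt apart were called divergent (minus strand to the left) or convergent. Overlapping and nested listed intervals were ordered by their left end. Regions joined clusters of a strand at most 1000 nt apart.

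Whole profiles were called shared between loci only where the starts, with both ends fixed, could be arranged in at least 100000 ways. Parts of profiles were called shared where a 40-nt stretch holding 10 to 30 starts was identical at another locus, which could be searched in 667 clusters. Only copies within the list can be seen this way. Shares carry 95% Wilson intervals and two-sided exact binomial tests, at a threshold of 0.05. Read numbers were permuted over the clusters 10000 times to test the highest mean of the megabases with 10 or more clusters. Intervals and tests cover counting error only, and clusters within a region are not independent. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

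The rule for named sites, fixed before the data were examined, was the 10 with the highest score where neither the list nor an annotation of its build named genes. Ties were broken by reads and then by position, and entries were counted once per cluster. Other sites and regions were named after their values were seen. Of the results planned before the data were examined, 6 were not run: the share of sites in 5' untranslated regions, position relative to the start codon, the m6A consensus motif, base composition, gene lists and agreement between replicates. The first 5 need an hg19 annotation or sequence, which were not used here, and the last needs replicates kept apart. Fixed gene lists were therefore not tested. Alternatives for the count of sites were a score at or above the median and merging of overlapping sites or of sites within 50 nt. The orientation, shortening, shared-profile and megabase analyses were chosen after seeing the data, as were the alternatives for orientation, shortening and shared profiles. No alternative was run for the megabase analysis.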

Results

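The series asked where eIF3a, a subunit of the translation initiation factor eIF3, contacts RNA, and where N6-methyladenosine (m6A) lies after heat shock, under a title about m6A in 5' untranslated regions and cap-independent translation. eIF3 is the large complex that helps to bring the small ribosomal subunit to an mRNA. The eIF3a data came from PAR-iCLIP in HEK293T, a human embryonic kidney cell line that carries the SV40 large T antigen. In this method cells take up 4-thiouridine, ultraviolet light joins the protein to RNA at the labelled bases, the protein is immunoprecipitated, and the attached RNA fragments are sequenced. Cells were labelled for 8 h and irradiated at 354 nm, and 2 replicates were made. The other 5 samples were m6A libraries made by miCLIP, in which an antibody against m6A is joined to RNA by ultraviolet light. They comprised 1 heat-shocked HEK293T sample, 2 heat-shocked samples of HepG2, a liver carcinoma line, and 2 HepG2 controls. Heat shock was 1 h at 42 °C with 6 h of recovery at 37 °C. The m6A libraries were not analysed here, so no comparison of heat shock with control was made.

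The eIF3a data consisted of 1 list of genomic intervals on hg19 for the whole series, which did not say which replicate a read came from. Each interval carried a score, the highest read coverage of the read cluster it belonged to, and the cluster's coverage profile. No value therefore had a replicate error, and the p-values below describe the placement of sites within this list, not the spread between cultures. Intervals and exact binomial tests cover counting error only. No hg19 gene annotation was used here, so sites are named by position, with the first and last listed base. Those ends are uncertain by 1 nt, because unshortened intervals were 1 nt shorter than their profiles. Gene identity, exon and untranslated-region status, distance to the start codon, sequence motifs and agreement between replicates were not analysed here.

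The list had entries on both strands in nearly equal numbers, and 0 entries on the mitochondrial genome. Its filters are unknown, so the 0 does not show an absence of contact there. The list held 4013 entries, 2041 on the plus strand and 1972 on the minus strand. Of these, 64 repeated another entry exactly, and many others were parts of the same read cluster. Counting the entries of 1 profile at 1 place once left 3604 clusters, 3566 of them on the primary chromosomes. The primary clusters were divided between 1797 on the plus strand and 1769 on the minus strand, with a median of 6 reads on each. A cluster on the primary chromosomes had a median length of 61 nt, with a range from 26 to 620 nt. The listed interval was shorter than its cluster by more than the usual 1 nt in 1920 entries (47.8%), and the median listed interval was 47 nt. For 1530 of all 3604 clusters (42.5%) no entry showed the full length, so the position of the summit within or beside the listed interval is unknown for them.

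Every one of the 3113 distinct coverage profiles could be split exactly into reads of 25 nt, which gave the number of reads behind each site. The clusters on the primary chromosomes held 38419 reads in all, with a median of 6 reads per cluster, quartiles of 4 and 12, and a range from 2 to 172. Reads common to overlapping clusters, or listed at several loci, are counted each time in that total. The reads were spread unevenly. The 356 clusters with the most reads held 37.5% of them. Scores ran from 2 to 24 with a median of 5, and 37 clusters scored 20 or more. Across clusters, which are not independent replicates, the score followed the number of reads with a Spearman's rho of 0.898. The score was bounded at its upper end where starts held 1 read each. Counting each distinct profile once over all sequences, 36882 occupied read starts held 1 read and 10 held 2. With 1 read per start, 25-nt reads cannot stack higher than 25. Clusters that scored 20 or more held between 28 and 172 reads (median 57). Those reads are counted over whole clusters of different lengths, so they do not measure how far the summits were compressed.

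**Figure D1:**
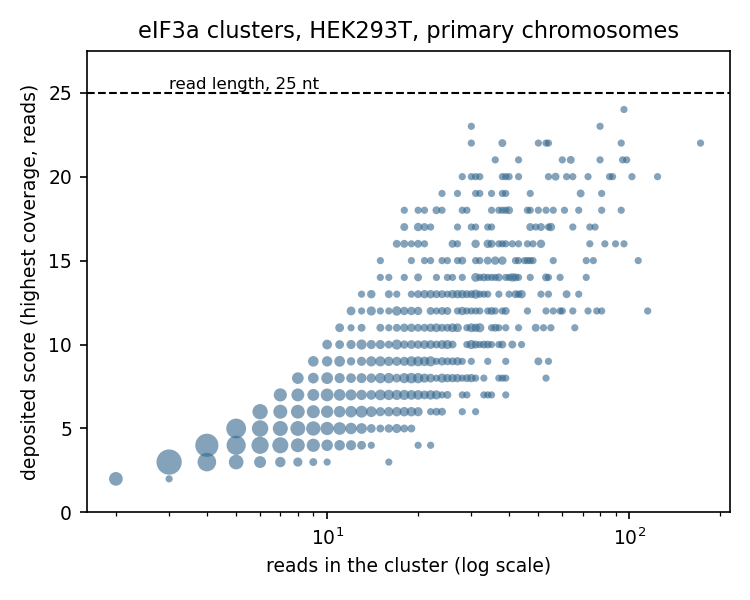
Deposited score (highest coverage, in reads) against the number of reads in the cluster on a log axis, for the 3566 eIF3a clusters on the primary chromosomes. Each point is a pair of values, larger where more clusters share it, and the dashed line marks the read length of 25 nt, below which all scores lie (highest 24).

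The 10 sites with the highest scores lay on chromosomes 1, 2, 5, 6, 11, 12 and 22. The highest score, 24, was on the plus strand of chromosome 22 at 24236565 to 24236661, in a cluster of 96 reads over 233 nt. A score of 23 was reached on the minus strand of chromosome 5 at 180670801 to 180670906, with 80 reads, and on the minus strand of chromosome 11 at 17099189 to 17099220, with 30 reads in a cluster of only 77 nt. The remaining 7 sites scored 22 and differed far more in reads than in score. The minus strand of chromosome 1 at 149814266 to 149814318 held 172 reads in a cluster of 522 nt, the most reads of any cluster, although only 53 nt of it were listed. The plus strand of chromosome 12 at 56510386 to 56510571 held 94 reads. The plus strand of chromosome 2 at 232573335 to 232573416 held 54 reads, and that of chromosome 6 at 62284022 to 62284156 held 53. The plus strand of chromosome 1 at 203830725 to 203830845 held 50 reads. The last pair were neighbours on the minus strand of chromosome 11, at 10529903 to 10529994 and at 10530059 to 10530177, with 38 reads each. None of the 10 profiles recurred in full at another locus of the list, although copies outside the list would not be seen. The cluster beside the chromosome 11 pair, at 10530205 to 10530346, shared a stretch of read starts with a listed locus on chromosome 5. Reads of that pair may therefore be less certain in their placement. The order among scores of 22 to 24 rests on differences of 1 or 2 reads at the summit.

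Some extended sites had many reads without a high summit; these and the regions named in the account of crowding, of chromosome 6 and of shared reads were chosen after their values were seen. The longest cluster, on the plus strand of chromosome 5 at 56471279 to 56471897, spanned 620 nt and held 115 reads, with a score of 12. A cluster of 318 nt on the minus strand of chromosome 12 at 57081782 to 57082098 held 107 reads with a score of 15. On the minus strand of chromosome 5 at 140699620 to 140700042, 81 reads were spread over 424 nt with a score of 12. On the minus strand of chromosome 1 at 115292451 to 115292827, 74 reads covered 378 nt with a score of 16.

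Chromosome 1 held the most clusters, 447 or 12.5% of those on the primary chromosomes, with 5247 reads. Chromosomes 2 and 3 had 242 clusters each, and chromosome 6 followed with 214. Chromosome 21 had 42. Chromosome 6 had the highest mean number of reads per cluster, 13.4, which rested on the 10 clusters between 27 and 28 Mb. Without them its mean was 11.8, below the 12.5 of chromosome 17. Chromosome 13 had the lowest mean, 8.37, while chromosome medians lay between 5 and 8 for all chromosomes but Y, which had 2 clusters. No difference between whole chromosomes was tested.

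**Figure D2:**
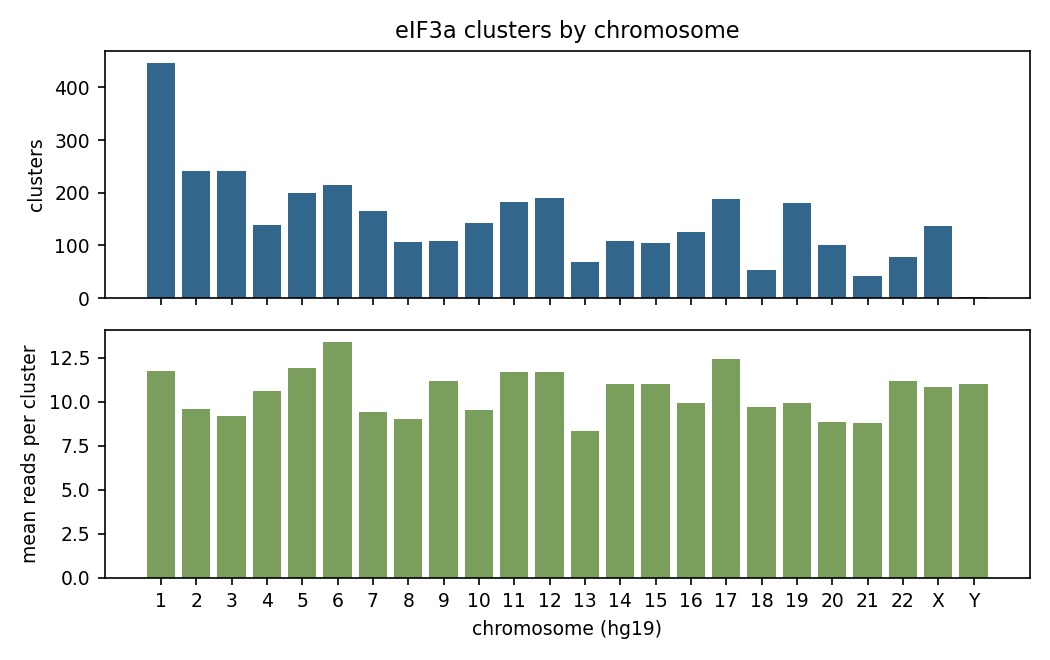
Number of eIF3a clusters (upper bars) and mean reads per cluster (lower bars) on each primary chromosome of hg19. Chromosome 1 has the most clusters, 447, and chromosome 6 the highest mean, 13.4 reads, or 11.8 without its 10 clusters at 27 to 28 Mb.

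Some sites had company on the same strand. Of the 667 gaps under 1000 nt between neighbours on a strand, 451 were under 100 nt. Whether such close clusters are separate sites or 1 sparsely covered stretch was not tested. Clusters less than 1 kb apart on a strand formed 2877 regions, of which 2361 held 1 cluster, 516 held 2 or more and 33 held 4 or more. The most crowded region was on the minus strand of chromosome 4 at 103747666 to 103749186, with 9 clusters and 82 reads. A region on the minus strand of chromosome 5 at 79945906 to 79946800 held 7 clusters with 122 reads, and part of its read pattern recurred on chromosome 11. The region with a pair of top sites, on the minus strand of chromosome 11 at 10529774 to 10530346, held 4 clusters with 146 reads. By megabase, 102 to 103 Mb of chromosome X had the most clusters, 19, with a mean of 8.58 reads.

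The interval from 27 to 28 Mb of chromosome 6 stood apart by reads rather than by number of clusters. Its 10 clusters held 452 reads, a mean of 45.2 and a median of 42.5, against a mean of 10.7 and a median of 6 in the 3556 other primary clusters. Of the 10, 6 held 40 or more reads, against 116 elsewhere (3.26%). Among the 22 megabases with 10 or more clusters this mean was the highest, and 10000 permutations of the read numbers over all primary clusters gave a highest mean as large with p = 0.0002 (one-sided). The permutation treats clusters as independent, which neighbouring clusters need not be. The neighbouring megabase, 26 to 27 Mb, came next with a mean of 25.1 over 16 clusters, and did not pass the same permutation test (p = 0.0761). Outside chromosome 6, 3 clusters between 149783879 and 149858232 on the minus strand of chromosome 1 held 94, 172 and 73 reads. That megabase had too few clusters to enter the test.

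Where neighbouring sites of the list lay on opposite strands, they nearly always pointed away from each other. On the primary chromosomes, 58 pairs of adjacent sites on opposite strands lay within 1 kb. In 56 of them the minus-strand site lay to the left and the plus-strand site to the right, and 2 had the reverse order. The divergent share was 96.6% (95% Wilson interval 88.3 to 99.0, two-sided exact binomial p = 1.19e-14 against equal shares). Equal shares may be no fair reference, because many intervals had been cut shorter than their clusters. A list limited to the 5' parts of transcription units could give this order without any preference of eIF3a. The divergent share was 88.9% for gaps of up to 200 nt (16 of 18 pairs) and 93.5% for gaps of up to 10000 nt (86 of 92 pairs). At up to 100000 nt it fell to 64.3% (202 of 314 pairs, interval 58.9 to 69.4). Part of this fall was built in. Along a chromosome, switches from minus to plus and from plus to minus alternate, so the shares approach equality as the allowed gap grows. Adjacent pairs can also share a site, so the binomial tests take as independent pairs that need not be. The 56 divergent pairs had a median gap of 298 nt, with quartiles of 178 and 443 nt.

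**Figure D3:**
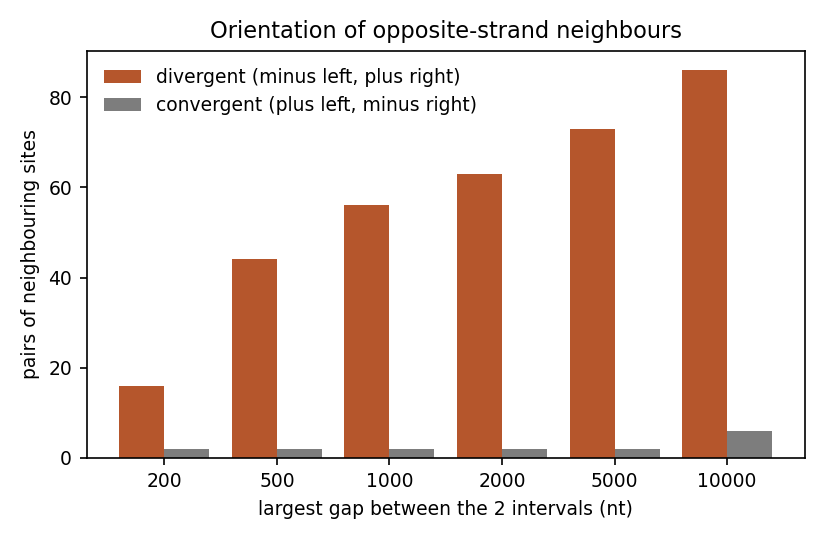
Pairs of adjacent eIF3a sites on opposite strands by the largest gap allowed between them, in nt, counted cumulatively. Divergent pairs outnumber convergent pairs at every distance shown, 56 to 2 at 1000 nt.

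The divergent pairs included 8 of the 10 clusters at 27 to 28 Mb of chromosome 6. The first pair had 102 reads on the minus strand at 27100530 to 27100575 and 55 on the plus strand at 27100817 to 27100850. The second had 98 reads on the minus strand at 27114578 to 27114637 and 42 on the plus strand at 27114884 to 27114907. At 27775685 to 27775707 the minus-strand site held 20 reads, and its plus-strand neighbour at 27775977 to 27775987 held 55. At 27860928 to 27860963 the minus-strand site held 31 reads, and its neighbour at 27861203 to 27861240 held 43. The gaps of these 4 pairs were 241, 246, 269 and 239 nt. All 8 listed intervals were short, 11 to 60 nt, while the clusters they came from were 83 to 314 nt long. In 3 of the 4 pairs the unlisted length exceeded the gap, so whether the clusters themselves overlapped is unknown.

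**Figure D4:**
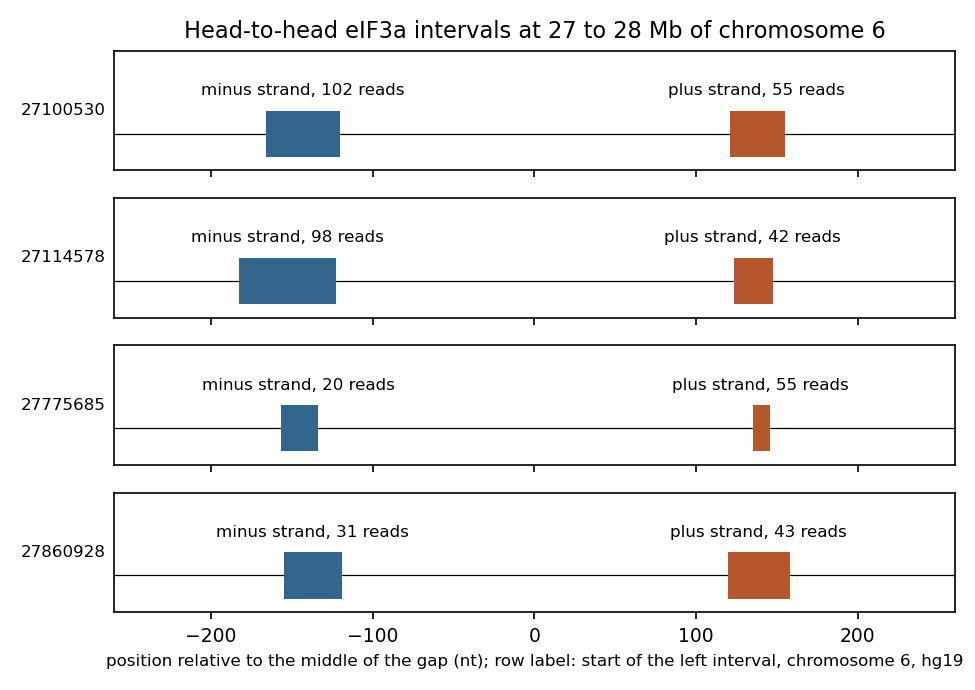
The 4 divergent pairs of eIF3a intervals at 27 to 28 Mb of chromosome 6 (hg19), drawn to scale in nt around the middle of each gap, with the reads of each cluster above its listed interval. Minus-strand intervals lie to the left and plus-strand intervals to the right, 239 to 269 nt apart.

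Where a cluster was listed both in full and in shortened form, the shortening was mostly at the downstream end. In 192 such clusters, 163 shortened intervals lacked only downstream sequence, 43 lacked only upstream sequence and 7 lacked both. The downstream share of the 206 intervals shortened on 1 side was 79.1% (95% Wilson interval 73.1 to 84.1, two-sided exact binomial p = 1.21e-17 against equal shares). Intervals of 1 cluster are not independent, and the share with 1 interval per cluster was 79.5%.

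Some reads were listed at more than 1 locus, which inflates counts of sites. Of all 3604 clusters, 1775 had read starts that could be arranged in at least 100000 ways, and 59 of these, 35 on primary chromosomes, had exactly the profile of another locus. They formed 22 sets, where 0.0026 matching pairs were expected by chance, and showed 1358 reads where counting each set once gave 430. Of the sets, 10 had a member outside the primary chromosomes and 12 lay on primary chromosomes alone. Sequences outside the primary chromosomes held 38 clusters, 30 of them on 7 alternate versions of part of chromosome 6, the major histocompatibility complex. All 24 of the 38 with so intricate a profile had a copy on a primary chromosome. The shared cluster with the most reads lay on the plus strand of chromosome 6 at 31795512 to 31795727, whose 124 reads, the second highest number, appeared at 5 loci with a score of 20. Those loci were chromosome 6 itself and alternate versions of it, with no other primary chromosome among them. The cluster of 8 reads at 31783382 to 31783430 of the same strand also appeared at 5 loci, again chromosome 6 and alternate versions of it. A cluster of 19 reads at 1510903 to 1510964 of chromosome X, minus strand, reappeared at 1460903 to 1460964 of chromosome Y. A further 10 clusters had a profile of their own but shared a 40-nt stretch of read starts with another locus. Among them were the minus-strand clusters at 10530205 to 10530346 of chromosome 11, with 39 reads, and at 79946319 to 79946477 of chromosome 5, with 46 reads.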

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

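The alternatives for the number of sites were planned except for the removal of repeats, the counts of clusters and of profiles, and all alternatives for orientation, shortening and shared profiles, which were chosen after seeing the data. The list held 4013 sites as deposited, and 2163 with a score at or above the median of 5, a fall that follows from the filter itself. The other 6 alternatives stayed within 1.5 times of the deposited number, the lowest being 3210 after merging sites within 50 nt and the highest 3949 without repeats. The divergent share stayed above 50% and past its threshold in all 10 alternatives (64.3% with gaps of up to 100000 nt, and 88.9% to 100% in the other 9, largest exact binomial p = 0.00131), over gaps, score filters, intricate single-locus pairs and the removal of 27 to 28 Mb of chromosome 6. The gap settings are nested and the other alternatives reuse the same pairs, so these are not separate checks. The downstream share of shortened intervals ranged from 78.8% to 79.5% over 4 alternatives. The number of clusters with a shared profile was 59, and 739 when simple profiles of few reads, which can match by chance, were let in. Other settings for untranslated regions, motifs, base composition, gene lists and replicate agreement, listed before the data were examined, were not run. No paired analysis was possible because the list keeps no replicates apart and the m6A libraries were not analysed here. Reads per cluster limit what can be said of single sites: the median cluster held 6, and library depth is unknown.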

Other observations

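All tests in this part were chosen after the results they bear on had been seen. Read starts within clusters tended to lie next to each other. Starts 1 nt apart occurred 1.49 times as often as after shuffling starts within their clusters, those 2 nt apart 1.31 times and those 3 nt apart 1.21 times.

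Neighbouring sites on opposite strands lay head to head in 56 of 58 pairs. Reads of 1 molecule reported on both strands at the same place would need the clusters to overlap. In 54 pairs the clusters could not overlap, even with all unlisted length in the gap, and 52 of these (96.3%) were divergent. Such overlap therefore cannot account for the order in those 52 pairs. The other 4 pairs, 3 of them at 27 to 28 Mb of chromosome 6, were all divergent and stay open. Leaving them out could only lower the share slightly, so 96.3% is no separate test of the order. Reads from opposite ends of a longer molecule need not overlap, and that case was not tested. As to reads placed at several copies of a sequence, 0 of the 58 pairs had a member found to share its reads with another listed locus. Simple profiles could not be judged this way, and copies outside the list would not be seen. In 21 pairs both sides had an intricate profile seen at 1 locus, and 20 of these (95.2%, exact binomial p = 2.1e-05) were divergent. With no shared pair to remove, that share cannot tell whether such placement matters. A candidate explanation is that the listed intervals lie in the 5' parts of transcription units, so that close opposite-strand neighbours come from divergent genes. In the 192 clusters listed both in full and shortened, 79.1% of the 206 intervals shortened on 1 side lacked the downstream end, which fits that hypothesis. The side is unknown for the 1530 clusters never listed in full. Reads alone would not shorten an interval, so the 1920 of 4013 entries shorter than their cluster argue against listing without any restriction, for those entries. What set the cuts is unknown, and so is whether the list was restricted to 5' parts. If it was, the head-to-head order could follow from the restriction and would not describe eIF3a. The list has no second group to compare.

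Sites at 27 to 28 Mb of chromosome 6 held the most reads per cluster among megabases with 10 or more clusters, a mean of 45.2. The window was narrowed from 26 to 28 Mb after the neighbouring megabase was seen not to pass. Chance over megabases, with clusters taken as independent, is argued against by the permutation p of 0.0002. The divergent pairs there need not be independent, and no other bin size or minimum number of clusters was run. Reads placed at several copies of a sequence are argued against by the finding that 0 of the 8 clusters of 20 or more reads there shared a profile or a stretch of starts with another listed locus (exact 95% upper limit 36.9%). As background not taken from an annotation of this build, this part of chromosome 6 is known for its clustered histone genes, many of them in divergent pairs. RNA abundance was not measured in the data used here, so high expression stays open as an untested explanation, and no biological explanation was tested.

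Read starts almost never repeated a position, although read stacks were dense. If 2 equally deep libraries had been collapsed to 1 read per start separately and then added, 2279.9 doubled starts were expected at the cluster summits (central 95% of 1000 simulations 2194 to 2366), and 7 were observed. Separate collapsing followed by addition is therefore argued against for libraries of equal depth. Collapsing after pooling, or a list made from 1 library, stays open. Separate collapsing of libraries of unequal depth was not simulated and stays open too. With so few doubled starts, the score may understate the difference between strong and weak sites, since 25-nt reads with 1 read per start cannot stack beyond 25.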
